A study of Mus musculus with 29 samples.

How the data were processed

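Whole blood was profiled by total RNA sequencing in 29 male mice of a strain given in the labels as LJ, with 1 library per animal. The animals were sampled at day 120 after 11.35 Gy of upper body irradiation or after a sham procedure, which has a dose of 0 Gy here. Blood was taken from the cheek or tail vein into PAXgene tubes, and globin and ribosomal transcripts were removed before stranded total RNA libraries were made. The labels give each animal an outcome, Live or Die. All sham animals have the label Live, so the 3 groups used here were sham (n = 10), irradiated animals with the label Live (n = 10) and irradiated animals with the label Die (n = 9). The labels name no batch and no sequencing date.

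The deposited values are a normalised signal per gene symbol, made by the authors from estimated counts and scaled for each library. The submitters' processing notes name bcl2fastq 2.19, kallisto 0.44.0, sleuth, DESeq2 and the mouse build GRCm38. The role and order of these tools and the annotation are not given in the sources used here. The table held 50384 gene symbols in 29 libraries. Over the genes above 0 in every library, the median ratio to the gene's geometric mean was 1.02 in all libraries, which is the scale that division by median-ratio size factors leaves. Between 3.92% and 18.2% of the values per library were whole numbers, within 0.01, after division by the apparent value of 1 read, so read counts were not recovered. The approximate number of reads per library, taken as the total divided by the value of 1 read, lay between 19.3 and 41.1 M. The values are called normalised counts below.

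Choices of test, filter, gene lists and named genes were made before the data were examined, with a test for counts and a test for normalised values written down in advance. Because the values were normalised, limma 3.58.1 in R 4.3.3 was used, with a trend, on log2(value + 0.5). All log2 changes are on that scale. The 24310 genes with a mean of at least 1 over the 29 libraries were tested in 1 model with 3 group means and no covariate. The contrasts were the equally weighted mean of both irradiated groups minus sham, Live minus sham, Die minus sham, and Die minus Live. Tests were two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. SE is the standard error from limma, and SD is the spread between animals of 1 group.

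The choice of genes to name was also fixed. For irradiated against sham and for Die against Live, the rule took up to 12 genes per direction with the largest change among those past the threshold, with a mean of at least 5 and a symbol other than a clone or model number. For the other contrasts it took up to 6. Where fewer passed, genes with the smallest unadjusted p were added until 5 per direction were reached, and most of them are named. Up to 4 members with the smallest p were named for each list described, and Cdkn1a, Mdm2, Hba-a1, Hbb-bs, S100a8, Cd79a, Cd3e and Pf4 were reported throughout. Coordinates are those of GENCODE M21 on GRCm38, in which 49678 of the symbols were found.

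The 39 gene lists, covering blood cell types, interferon, DNA damage, cell cycle, inflammation, metabolism and tissue markers, held 747 distinct symbols, of which 746 were found, 18 of them through an older symbol. Some genes stand in more than 1 list, such as Csf1r and Lyz2. Each list was tested with limma's camera with an inter-gene correlation preset at 0.01 and, beside it, with an estimated correlation, both adjusted over the 39 lists within a contrast. A test that treats the animal as the unit was added after the data were seen. It permuted group labels over the mean centred log2 value of a list per library. It was an exact permutation test where 2 groups were compared and at least 1 had 9 animals or fewer, as in all comparisons without the 3 libraries below, and otherwise a permutation test with 100000 draws.

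Outcome among the 19 irradiated animals was classified with 1 animal left out at a time, with the 20 genes of smallest p chosen inside each fold and a nearest diagonal centroid. Balanced accuracy was compared with 100 permutations of the outcome labels, one-sided. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for permutations and classification, and matplotlib 3.10.9 for plots. The limma step was tested on simulated data in which 200 of 24310 genes were changed. For a change of 1 on the log2 scale it recovered 44.5% of these genes for irradiated against sham, 32.0% for Live against sham, 26.0% for Die against sham and 33.0% for Die against Live. For a change of 2 it recovered 84.0%, 80.5%, 75.0% and 73.0% in the same order, and between 1.11% and 5.81% of the calls were wrong. The changed genes were drawn only from those with a mean of at least 50, with noise independent between genes. Recovery of genes with lower means was not tested. The classifier was tested on simulated data with 5000 genes and reached a balanced accuracy of 43.4% with no changed gene and 100% with 200 genes raised by 2 SD.

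Alternatives covered the pseudocount, the minimum mean, quantile normalization, array weights, covariates for depth and composition, removal of hemoglobin or erythroid genes with rescaling, the fit to only the groups compared, a block for the replicate number that sham and irradiated animals share, a stricter threshold and the removal of each library. Alternatives added after the data were seen were removal of the 3 libraries with most expressed genes at 0, a minimum mean of 50, a pseudocount of 10, the share of 7S RNA as a covariate and the permutation of animals. Shares of library composition were compared between groups by permutation, adjusted over 6 measures. No sample and no column of the table was left out of the main comparisons.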

Results

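Gene expression in whole blood was measured in 10 sham animals, 10 irradiated animals with the outcome Live and 9 irradiated animals with the outcome Die. Approximate depth was 24.7 ± 3.43 M reads (SD, n = 10) in sham, 29.5 ± 6.11 M reads (SD, n = 10) in Live and 26.6 ± 4.22 M reads (SD, n = 9) in Die animals. The number of genes above 0 per library ranged from 14975 to 24275. Hemoglobin transcripts, the main message of red cells and the target of the globin removal, took 1.90% to 7.44% of the values per library. The 7S RNA genes Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, took 17.9% ± 6.57 (SD, n = 10) of the values in sham, 27.4% ± 9.34 (SD, n = 10) in Live and 14.2% ± 10.8 (SD, n = 9) in Die animals. In 3 libraries many expressed genes, taken as the 11519 with a mean of at least 50, were listed at 0. These were sham replicate 1 with 828 such genes, Die replicate 2 with 754 and Die replicate 14 with 506, against at most 220 in any other library.

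The first comparison asked how blood differed from sham at day 120 after upper body irradiation, whatever the outcome. The 4 genes that passed are genes of monocytes and other phagocytes, all lower in irradiated animals. Cx3cr1, the fractalkine receptor of patrolling monocytes, fell by 1.36 ± 0.20 (log2, SE, adjusted p = 0.00257), from a mean normalised count of 1059 ± 378 (SD, n = 10) in sham to 368 ± 142 (SD, n = 10) in Live and 452 ± 131 (SD, n = 9) in Die animals. Cd177, a surface protein of neutrophils, fell by 1.36 ± 0.23 (SE, adjusted p = 0.0167), from 1142 ± 356 in sham to 400 ± 229 in Live and 542 ± 171 in Die animals. Mpeg1, which encodes the pore-forming protein perforin-2 of macrophages and other phagocytes, fell by 1.06 ± 0.19 (SE, adjusted p = 0.0167), and Cybb, the catalytic subunit of the phagocyte NADPH oxidase, fell by 0.84 ± 0.15 (SE, adjusted p = 0.0180). The value was below the sham median in 19 of 19 irradiated animals for Cx3cr1, Cd177 and Mpeg1, and in 17 of 19 for Cybb.

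On GRCm38 the 4 protein-coding genes lie on chromosome 9 from 119901616 to 120069879 (Cx3cr1), chromosome 7 from 24743983 to 24760311 (Cd177), chromosome 19 from 12460779 to 12465283 (Mpeg1) and chromosome X from 9435252 to 9487771 (Cybb). The next gene in the downward direction did not pass. It was Ccr2, the chemokine receptor by which classical monocytes leave the bone marrow (chromosome 9, 124101950 to 124113557), with a log2 change of -1.06 ± 0.21 (SE, adjusted p = 0.0521). The genes with the smallest p in the upward direction did not pass either. Carmil1, a regulator of actin capping protein (chromosome 13, 24012344 to 24280795), had a log2 change of 1.52 ± 0.31 (SE, adjusted p = 0.0641). Others, with adjusted p between 0.169 and 0.186, were Lactb2 (1.05), Rnf19a (0.66) and Usf3 (0.59).

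**Figure D1:**
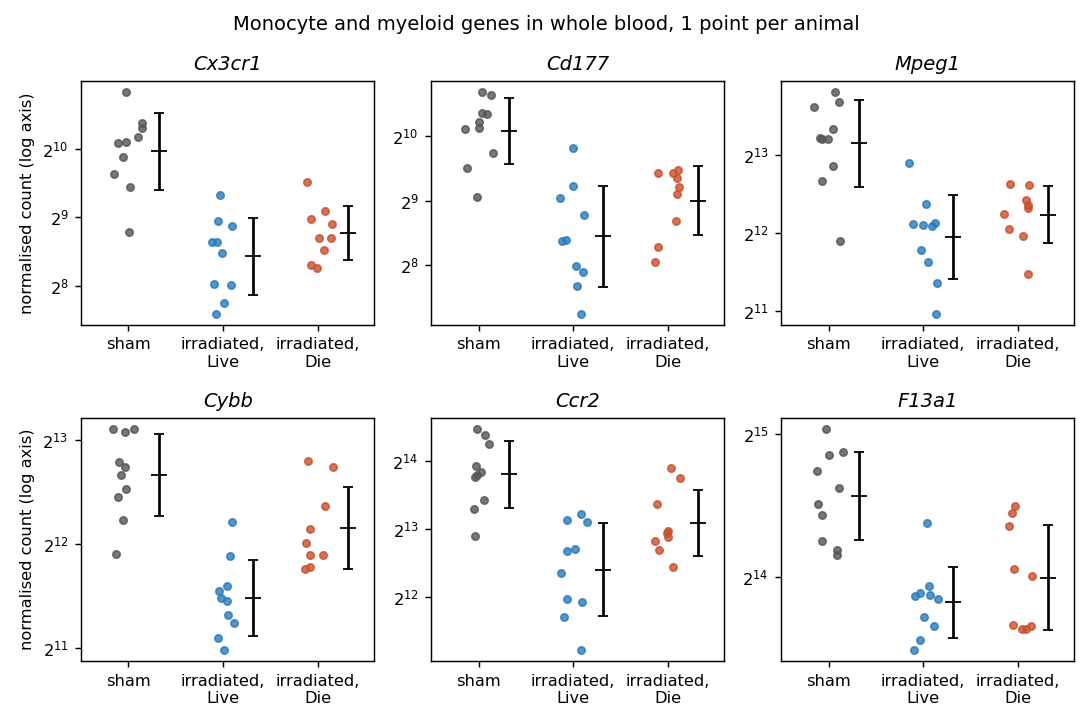
Normalised counts (log axis) of 6 monocyte and myeloid genes in each animal by group, with the mean and SD of the log2 values beside the points. For Cx3cr1, Cd177, Mpeg1 and F13a1, 19 of 19 irradiated animals lay below the sham median.

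Among the fixed lists, classical monocyte markers fell by a median of 0.85 (log2), with 13 of 13 members below 0 (preset correlation, adjusted p = 4.81e-20, adjusted p = 0.0282 with an estimated correlation). Of these 13, 11 were lower when adjusted over the list alone and 0 over all genes. Examples are Ccr2, F13a1, a coagulation factor made by monocytes (-0.66), the membrane protein gene Ms4a6c (-0.89) and the lectin receptor gene Clec4a3 (-0.82). The list was below the sham median in 19 of 19 irradiated animals, and with animals as the unit its mean difference was -0.83 (permutation test, adjusted p = 0.0152). Non-classical monocyte markers fell by a median of 0.49, with 12 of 12 members below 0 (adjusted p = 2e-07, adjusted p = 0.0483 with an estimated correlation). In that list 3 members were lower when adjusted over the list alone and 1 over all genes, with Cx3cr1, the adhesion receptor gene Adgre4 (-0.83) and Csf1r, the receptor for the monocyte growth factor CSF1 (-1.15), as examples. With animals as the unit this list was not past the threshold (mean difference -0.51, permutation test, adjusted p = 0.402). Unfolded protein response genes fell by a median of 0.21, with 15 of 20 members below 0 (adjusted p = 0.000723, adjusted p = 0.0483 with an estimated correlation). Of these, 2 were lower when adjusted over the list alone and 0 over all genes, the chaperone gene Hspa5 (-0.58) and the stress transcription factor gene Atf3 (-1.18). This list did not pass either with animals as the unit (mean difference -0.17, permutation test, adjusted p = 0.575).

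Other lists with lower medians passed only with the preset correlation. Dendritic cell markers had a median of -0.49 (adjusted p = 0.00537, adjusted p = 0.117 with an estimated correlation). Flt3, a growth factor receptor of dendritic cell precursors (-1.14), and the transcription factor gene Irf8 (-0.54) were lower when adjusted over the list alone, 2 genes against 0 over all genes. Complement and Fc receptor genes had a median of -0.44 (adjusted p = 0.000836, adjusted p = 0.257 with an estimated correlation). Adjusted over the list alone 4 were lower, against 0 over all genes, among them the complement component gene C3 (-1.16), Itgam (-0.79) and Fcgr1 (-1.21). TLR and inflammasome genes had a median of -0.30 (adjusted p = 0.000357, adjusted p = 0.273 with an estimated correlation). In it 1 gene, Tlr2, a receptor for bacterial lipoproteins (-0.81), was lower when adjusted over the list alone and 0 over all genes. Immature granulocyte markers had a median of -0.80 (adjusted p = 0.0184, adjusted p = 0.273 with an estimated correlation). Adjusted over the list alone 3 of them were lower and over all genes 0, the granule protease gene Ctsg (-2.39), the chitinase-like gene Chil3 and the lysozyme gene Lyz2 (-0.60). Neutrophil markers had a median of -0.20 (adjusted p = 0.0327, adjusted p = 0.721 with an estimated correlation). Neutrophil activation genes had a median of -0.14 (adjusted p = 0.0184, adjusted p = 0.563 with an estimated correlation). In each of these 2 lists Cd177 and Mmp8 (-0.64), a neutrophil collagenase, were lower when adjusted over the list alone, 2 genes against 1 over all genes. Hypoxia and glycolysis genes had a median of -0.17 (adjusted p = 0.0418, adjusted p = 0.467 with an estimated correlation). The glycolytic enzyme gene Eno1 (-0.62) was the 1 lower gene adjusted over the list alone and 0 over all genes.

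Higher medians came from 4 of the 14 lists past the threshold, all with the preset correlation only. Mitochondrially encoded genes had a median of 0.52 (adjusted p = 2.27e-06, adjusted p = 0.176 with an estimated correlation). Of these, 7 of 13 were higher when adjusted over the list alone and 0 over all genes, among them mt-Cytb (0.51) and mt-Co3 (0.53). Cell cycle genes had a median of 0.30 (adjusted p = 0.000273, adjusted p = 0.368 with an estimated correlation). The median was 0.18 for B cell markers (adjusted p = 0.00702, adjusted p = 0.467 with an estimated correlation) and 0.17 for cytosolic ribosomal protein genes (adjusted p = 7.95e-05, adjusted p = 0.530 with an estimated correlation). In these 3 lists 0 genes passed, whether adjusted over the list alone or over all genes. The share of mt-Rnr2, the large mitochondrial ribosomal RNA, was 4.30% ± 1.57 (SD, n = 10) in sham, 7.09% ± 2.41 (SD, n = 10) in Live and 7.68% ± 6.14 (SD, n = 9) in Die animals.

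The other 25 lists did not pass in this comparison. Their adjusted p lay between 0.0550 and 0.907 and their medians between -0.36 and 0.23. They were the lists for platelets, erythroid cells, heme synthesis, plasma cells, T cells, cytotoxic lymphocytes, natural killer cells, regulatory and activated T cells, eosinophils, basophils and mast cells, stem and progenitor cells, endothelium, and lung epithelium with alveolar macrophages. The rest were MHC class II, type I interferon, interferon gamma, p53 targets, DNA damage repair, replication-dependent histones, inflammatory cytokines, TGF-beta signalling and matrix, the Nrf2 response, heat shock and immediate early genes, nuclear oxidative phosphorylation and apoptosis. The median, mean and test direction differed in sign for Nrf2 response genes, MHC class II genes, histones, heme enzymes, nuclear oxidative phosphorylation genes and lung markers. Of the genes fixed for every comparison, the p53 targets Cdkn1a (log2 change 1.55 ± 0.88, SE, adjusted p = 0.763) and Mdm2 (0.12 ± 0.14, SE, adjusted p = 0.905) did not pass. Neither did the hemoglobin genes Hba-a1 (0.30) and Hbb-bs (0.33), whose near-identical copies share reads, nor S100a8 of neutrophils (0.34), Cd79a of B cells (-0.08), Cd3e of T cells (0.46) and Pf4 of platelets (0.42), with adjusted p between 0.670 and 0.964.

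Of 24310 genes tested with limma for irradiated against sham, 0 were higher and 4 lower, and 1799 had an unadjusted p under 0.05 where 1216 would do so by chance. The count was 66 without sham replicate 1, 62 without the 3 libraries with many genes at 0, 7 without Die replicate 2, Die replicate 15 or Live replicate 17, and 1 without sham replicate 4, 5, 6 or 7. It was 481 with array weights, 40 with the 7S share as a covariate, 28 with composition covariates, 10 with a minimum mean of 50, 1 with the number of reads as a covariate or an adjusted p under 0.01, and 0 with the shared replicate number as a block. The block fit held only animals whose number occurs in both groups, so fewer libraries than the reported fit.

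The second comparison took the animals whose outcome was Live, and addressed the state of their blood at day 120. The same 4 genes were again lower. Cx3cr1 fell by 1.53 ± 0.23 (log2, SE, adjusted p = 0.00175) and Cybb by 1.18 ± 0.17 (SE, adjusted p = 0.00174), from 6689 ± 1716 normalised counts (SD, n = 10) in sham to 2951 ± 808 (SD, n = 10) in Live animals. Ccr2 fell by 1.40 ± 0.24 (SE, adjusted p = 0.00592), from 15092 ± 4928 in sham to 5953 ± 2569 in Live animals, and lay below every sham animal in 7 of 10. Cd177 fell by 1.64 ± 0.27 (SE, adjusted p = 0.00497), Mpeg1 by 1.21 ± 0.21 (SE, adjusted p = 0.0113) and F13a1 by 0.75 ± 0.15 (SE, adjusted p = 0.0401). The remaining lower genes were Olfm1, a secreted olfactomedin (-1.62, adjusted p = 0.0380), Rnd3 (-1.46, adjusted p = 0.0316), and Abca9, a membrane transporter of the ABC family (-1.38, adjusted p = 0.0316). Each of these 9 genes was below the sham median in 10 of 10 Live animals, apart from Olfm1 with 9.

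Carmil1 rose by 1.77 ± 0.35 (SE, adjusted p = 0.0380), from 87.8 ± 35.8 normalised counts (SD, n = 10) in sham to 313 ± 193 (SD, n = 10) in Live animals, with 10 of 10 above the sham median. The next genes upward did not pass, with adjusted p between 0.0917 and 0.124. Among them were the transcription factor gene Elf2 (0.88), the dystrobrevin gene Dtnb (0.79) and Gng11, a G protein subunit of platelets (0.92). The fixed genes Pf4 (0.83 ± 0.23, SE, adjusted p = 0.201), Cdkn1a (1.91), Hba-a1 (0.63), Hbb-bs (0.47), Cd3e (0.41), Cd79a (0.31), S100a8 (0.30) and Mdm2 (-0.0033) did not pass. Their adjusted p values were at least 0.201.

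Classical monocyte markers fell by a median of 1.14 in Live animals, with 13 of 13 members below 0 (adjusted p = 1.03e-22, adjusted p = 0.0148 with an estimated correlation). Adjusted over the list alone 12 were lower, and over all genes 2, Ccr2 and F13a1. Clec4a3 (-1.14) and the matrix proteoglycan gene Vcan (-1.78) were further members. With animals as the unit the mean difference was -1.04 (permutation test, adjusted p = 0.0195), and 10 of 10 Live animals lay below the sham median. Non-classical monocyte markers had a median of -0.44 (adjusted p = 8.71e-06, adjusted p = 0.133 with an estimated correlation), with 3 lower when adjusted over the list alone and 1 over all genes. Between animals the mean difference was -0.47 (permutation test, adjusted p = 0.301), and -0.64 without the 3 libraries with many genes at 0 (exact permutation test, adjusted p = 0.0464). Unfolded protein response genes had a median of -0.25 (adjusted p = 0.00105, adjusted p = 0.0999 with an estimated correlation). Hspa5 (-0.69), the chaperone gene Hsp90b1 (-0.74) and Atf3 (-1.60) made 3 lower genes adjusted over the list alone and 0 over all genes. TLR and inflammasome genes had a median of -0.31 (adjusted p = 0.000920, adjusted p = 0.335 with an estimated correlation), with Tlr2 (-0.88) the 1 lower gene adjusted over the list alone and 0 over all genes. Complement and Fc receptor genes had a median of -0.32 (adjusted p = 0.0151, adjusted p = 0.392 with an estimated correlation), with 4 lower and 1 higher adjusted over the list alone and 0 over all genes.

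Of the 15 lists past the threshold in Live animals, the 10 with higher medians passed with the preset correlation only. Cytosolic ribosomal protein genes had 40 of 40 members above 0 and a median of 0.40 (adjusted p = 1.47e-14, adjusted p = 0.275 with an estimated correlation). In it 1 gene, Rps20 (0.56), was higher when adjusted over the list alone and 0 over all genes. Platelet and megakaryocyte markers had a median of 0.26 (adjusted p = 0.000178, adjusted p = 0.503 with an estimated correlation). Gng11 and Pf4, 2 genes, were higher when adjusted over the list alone and 0 over all genes. MHC class II genes had 10 of 10 members above 0 and a median of 0.30 (adjusted p = 0.00254, adjusted p = 0.503 with an estimated correlation), and H2-Ob (0.52) was the 1 gene higher when adjusted over the list alone, with 0 over all genes. The p53 targets had a median of 0.21 (adjusted p = 0.00590, adjusted p = 0.275 with an estimated correlation), with Ckap2, which encodes a spindle-associated protein (1.21), the 1 gene higher when adjusted over the list alone, with 0 over all genes. Cell cycle genes had a median of 0.52 (adjusted p = 1.14e-06, adjusted p = 0.275 with an estimated correlation). Mitochondrially encoded genes had a median of 0.46 (adjusted p = 0.000837, adjusted p = 0.335 with an estimated correlation) and B cell markers 0.27 (adjusted p = 0.000797, adjusted p = 0.335 with an estimated correlation). Replication-dependent histones had a median of 0.49 (adjusted p = 0.00922, adjusted p = 0.503 with an estimated correlation). Erythroid markers had a median of 0.25 (adjusted p = 0.00655, adjusted p = 0.662 with an estimated correlation) and nuclear oxidative phosphorylation genes 0.12 (adjusted p = 0.0280, adjusted p = 0.503 with an estimated correlation). In these last 6 lists 0 genes were called, adjusted over the list alone or over all genes. With composition covariates the median became -0.06 for B cell markers, -0.15 for MHC class II genes and -0.11 for histones, and with the number of reads as a covariate it became -0.11 for histones. With the 7S share as a covariate it became -0.17 for histones. Without the 3 libraries with many genes at 0 the mean difference between animals went from 0.65 to 0.28 for histones, from 0.42 to 0.29 for ribosomal proteins and from 0.27 to 0.18 for MHC class II genes. For complement and Fc receptor genes it went from -0.13 to -0.24. The share of 7S RNA was higher in Live than in sham by 9.48 percentage points (permutation test, p = 0.0174, adjusted p = 0.0521), and that of mt-Rnr2 by 2.79 (permutation test, p = 0.00531, adjusted p = 0.0319). Approximate reads were higher in Live than in sham by 4.77 M (permutation test, p = 0.0434, adjusted p = 0.0868). The ribosomal protein, histone and MHC class II scores followed the log2 of the 7S share over the 29 libraries (r = 0.886, 0.906 and 0.846). For MHC class II genes the relation was absent within Live animals (r = 0.000682). Library composition may therefore contribute to the higher medians of these 3 lists in Live animals.

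Of 24310 genes tested for Live against sham, 1 was higher and 9 lower, and 1868 had an unadjusted p under 0.05. The count was 50 without sham replicate 10, 41 without sham replicate 1, 39 without Live replicate 17, 6 without sham replicate 9, and 5 without sham replicate 2, 4, 6 or 7 or Live replicate 18 or 19. It was 716 with array weights, 115 without the 3 libraries with many genes at 0, 73 with the 7S share as a covariate, 40 with a minimum mean of 50, 39 with composition covariates, 4 at an adjusted p under 0.01, 3 with the number of reads as a covariate and 0 with the replicate number as a block. Here too the block fit held only animals with a number in both groups.

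The third comparison took the animals whose outcome was Die. Cx3cr1 was again among the genes with the smallest p, at -1.19 ± 0.24 (log2, SE, adjusted p = 0.151), and 9 of 9 Die animals lay below the sham median. It did not pass, and neither did Cln8, a protein of the endoplasmic reticulum, at -1.42 ± 0.27 (SE, adjusted p = 0.151), from 1043 ± 275 normalised counts (SD, n = 10) in sham to 417 ± 193 (SD, n = 9) in Die animals. Cln8 lay below every sham animal in 8 of 9 Die animals, a count that follows in part from its choice by smallest p. Cotl1, which encodes an actin-binding protein, was at -0.86 ± 0.17 (SE, adjusted p = 0.151), Cebpa, a transcription factor of myeloid differentiation, at -1.45 ± 0.32 (SE, adjusted p = 0.349) and Eno1 at -0.70 (adjusted p = 0.444).

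Upward, the genes with the smallest p in Die animals were Lactb2 (1.49 ± 0.31, SE, adjusted p = 0.210), the condensin subunit gene Ncapg2 (1.41, adjusted p = 0.226), the mitochondrial carrier gene Slc25a40 (1.18, adjusted p = 0.394), the histone deubiquitinase gene Mysm1 (0.89, adjusted p = 0.444) and Wasl, an activator of actin branching (0.80, adjusted p = 0.444). The fixed genes Cdkn1a (1.20), Cd3e (0.50), Cd79a (-0.47), S100a8 (0.38), Mdm2 (0.24), Hbb-bs (0.19), Hba-a1 (-0.04) and Pf4 (0.01) did not pass either. Of the genes that fell in Live animals, Cd177 was at -1.08, Mpeg1 at -0.92 and Cybb at -0.50 in Die animals, where a like sign is expected because the sham animals are shared.

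All list calls for Die against sham rested on the preset correlation. Classical monocyte markers had a median of -0.65 with 13 of 13 members below 0 (adjusted p = 3.05e-08, adjusted p = 0.224 with an estimated correlation). In it 7 genes, among them F13a1 (-0.57), Csf1r (-1.16) and Ccr2 (-0.72), were lower when adjusted over the list alone and 0 over all genes. With animals as the unit the mean difference was -0.63 (exact permutation test, p = 0.0127, adjusted p = 0.347), and it was -0.72 without the 3 libraries with many genes at 0 (exact permutation test, adjusted p = 0.0375). Non-classical monocyte markers had a median of -0.61 (adjusted p = 1.15e-05, adjusted p = 0.224 with an estimated correlation), with 4 lower when adjusted over the list alone and 0 over all genes. Its mean difference between animals was -0.55 (exact permutation test, adjusted p = 0.347), and -0.54 without those libraries (exact permutation test, adjusted p = 0.0307). Dendritic cell markers had a median of -0.70 (adjusted p = 0.00842, adjusted p = 0.224 with an estimated correlation). Flt3 (-0.98), the tetherin gene Bst2 (-2.24) and Irf8 (-0.56), 3 genes, were lower when adjusted over the list alone. Mitochondrially encoded genes had a median of 0.58 (adjusted p = 9.23e-06, adjusted p = 0.224 with an estimated correlation), with mt-Atp6 the 1 gene higher when adjusted over the list alone (adjusted p = 0.0431). None of the 12 lists had a member past the threshold over all genes, a count of 0 in each.

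Complement and Fc receptor genes had a median of -0.45 (adjusted p = 0.00345, adjusted p = 0.271 with an estimated correlation), with C3 (-1.02) and Cfp (-2.33), 2 genes, lower when adjusted over the list alone. Neutrophil activation genes had a median of -0.36 (adjusted p = 0.00544, adjusted p = 0.451 with an estimated correlation). TLR and inflammasome genes had a median of -0.20 (adjusted p = 0.0113, adjusted p = 0.451 with an estimated correlation) and hypoxia and glycolysis genes -0.22 (adjusted p = 0.0153, adjusted p = 0.451 with an estimated correlation). In each of these 3 lists 1 gene was lower when adjusted over the list alone, Cd177, Tlr2 (-0.74) and Eno1. Immature granulocyte markers had a median of -0.76 (adjusted p = 0.0115, adjusted p = 0.271 with an estimated correlation). Plasma cell markers had a median of -0.41 (adjusted p = 0.0258, adjusted p = 0.451 with an estimated correlation), MHC class II genes -0.30 (adjusted p = 0.0258, adjusted p = 0.578 with an estimated correlation) and unfolded protein response genes -0.21 (adjusted p = 0.0212, adjusted p = 0.224 with an estimated correlation). None of their members was called, adjusted over the list alone or over all genes. Without the 3 libraries with many genes at 0 the mean difference between animals went from -0.52 to -0.25 for plasma cell markers and from -0.34 to -0.14 for MHC class II genes. It went from -0.36 to -0.12 for neutrophil activation genes, from -0.31 to -0.19 for TLR and inflammasome genes and from -0.83 to -0.58 for immature granulocyte markers.

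Of 24310 genes tested with limma for Die against sham, 0 passed, and 2108 had an unadjusted p under 0.05. The count was 20 without sham replicate 1 and 2 without Die replicate 11, and 12 lists passed with the preset correlation, or 7 without Die replicate 14. It was 8 with array weights or with composition covariates, 2 with array weights without the 3 libraries with many genes at 0, and 1 with the number of reads as a covariate.

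Because both irradiated groups were set against the same sham animals, their log2 changes share error. The changes of Live and Die animals correlated across 24310 genes with r = 0.359, where genes are not independent replicates. A simulation of unchanged groups with the shared sham animals gave a mean r of 0.448 over 50 runs. Its noise was independent between genes, so it does not give the spread of r in libraries whose genes move together. With 5 sham animals for each group, so that none were shared, r was -0.103 for one division of the sham animals and 0.0376 for the other. Calls shared by both comparisons numbered 0, as Die against sham had none. The 9 genes called lower in Live animals all had negative changes in Die animals too, where the shared sham animals favour a like sign. These values do not decide whether the groups share a response. The difference between the irradiated groups is tested next.

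The fourth comparison, Die against Live among irradiated animals, addressed the aim given for the series, markers of survival in delayed lung injury, and also tests whether the response to irradiation differed by outcome. No single gene passed. The smallest adjusted p, 0.305, belonged to Tafa1, a secreted protein best known from brain, at 4.33 ± 0.89 (log2, SE), and to Rundc3a at -3.91 ± 0.80 (SE). Tafa1 had low values, 0.772 ± 1.22 normalised counts (SD, n = 10) in Live and 59.7 ± 117 (SD, n = 9) in Die animals, with 367 in Die replicate 14. Among genes with higher values, Ubxn4, a factor of protein degradation at the endoplasmic reticulum (0.86 ± 0.20, SE), and Arhgap26 (0.94 ± 0.23, SE), lay above the Live median in 9 of 9 Die animals, each with an adjusted p of 0.348. Serpine2, an inhibitor of thrombin (-0.87 ± 0.21, SE, adjusted p = 0.348), lay below the Live median in 8 of 9. These genes were named for their small p in this same comparison, so such counts of animals are no further support.

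Other genes named by the rule also had an adjusted p of 0.348. They were Olfr904 (2.98), the single-strand DNA-binding protein gene Nabp1 (0.79), Cdc42ep5 (-1.27), the separase gene Espl1 (-1.50) and the kinase gene Dyrk4 (-3.39). Dyrk4 also had low values, 14.05 ± 13.3 normalised counts (SD, n = 10) in Live and 0.991 ± 2.97 (SD, n = 9) in Die animals. In sham animals it was at 1.47 ± 3.14 (SD, n = 10), so Live was the group with higher values. Cybb, lower in Live than in sham, was higher in Die than in Live animals by 0.67 ± 0.18 (SE, adjusted p = 0.348), which did not pass. The fixed genes were Pf4 at -0.82 ± 0.24 (SE, adjusted p = 0.348), Cd79a at -0.78 (adjusted p = 0.371), Cdkn1a at -0.70, Hba-a1 at -0.67, Hbb-bs at -0.28, Mdm2 at 0.24, Cd3e at 0.09 and S100a8 at 0.07, and none passed. For Pf4 too Live was the group with higher values, with means of 8317 normalised counts in sham, 14032 in Live and 7996 in Die animals.

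The 10 lists past the threshold for Die against Live all rested on the preset correlation. Cytosolic ribosomal protein genes had 34 of 40 members below 0 and a median of -0.54 (adjusted p = 4.11e-12, adjusted p = 0.557 with an estimated correlation). Of these, 21, among them Rplp1 (-1.04) and Rps14 (-1.35), were lower when adjusted over the list alone and 0 over all genes. Their many pseudogenes share sequence with them. MHC class II genes, which present antigen to helper T cells, had 10 of 10 members below 0 and a median of -0.49 (adjusted p = 7.85e-07, adjusted p = 0.557 with an estimated correlation). Of these, 7, among them H2-Eb1 (-0.71) and Cd74 (-0.48), were lower when adjusted over the list alone and 0 over all genes. Replication-dependent histones had a median of -1.06 (adjusted p = 2.71e-05, adjusted p = 0.557 with an estimated correlation), which became 0.35 with the 7S share as a covariate. Platelet and megakaryocyte markers had a median of -0.21 (adjusted p = 0.000557, adjusted p = 0.643 with an estimated correlation). Of these, 5 were lower when adjusted over the list alone and 0 over all genes. Examples are Pf4 and the genes Gp9 (-1.28) and Gp1bb, which encode subunits of the von Willebrand factor receptor.

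Of these 10 lists, classical monocyte markers were the 1 with a higher median in Die than in Live animals, 0.32 (adjusted p = 0.00110, adjusted p = 0.603 with an estimated correlation). In it 4 members, Ifi204 (0.91), Vcan (1.12), Ccr2 (0.68) and Clec4a3 (0.64), were higher when adjusted over the list alone and 0 over all genes. Cytotoxic lymphocyte markers had a median of -0.65 (adjusted p = 0.00137, adjusted p = 0.557 with an estimated correlation), with the chemokine gene Ccl5 (-1.04) the 1 gene lower when adjusted over the list alone and 0 over all genes. Plasma cell markers had a median of -0.61 (adjusted p = 0.00874, adjusted p = 0.557 with an estimated correlation). Erythroid markers had a median of -0.27 (adjusted p = 0.00762, adjusted p = 0.643 with an estimated correlation), nuclear oxidative phosphorylation genes -0.26 (adjusted p = 0.00304, adjusted p = 0.603 with an estimated correlation) and cell cycle genes -0.21 (adjusted p = 0.00818, adjusted p = 0.643 with an estimated correlation). In these last 4 lists and in the histones 0 members were called, adjusted over the list alone or over all genes. With animals as the unit 0 of 39 lists passed (exact permutation test, smallest adjusted p = 0.119), and 10 had an unadjusted p under 0.05. Those were not the same 10 lists. Classical monocyte markers (exact permutation test, p = 0.0774), platelet markers (p = 0.0804) and erythroid markers (p = 0.443) were not among them. Without sham replicate 1, Die replicate 2 and Die replicate 14 the mean difference between animals went from -1.13 to -0.44 for histones, from -0.81 to -0.47 for cytotoxic lymphocyte markers and from -0.70 to -0.35 for plasma cell markers. It went from -0.61 to -0.32 for MHC class II genes, from -0.50 to -0.33 for ribosomal proteins and from -0.24 to -0.15 for nuclear oxidative phosphorylation genes. For the other 4 lists it changed little, as for classical monocyte markers (0.42 and 0.44) and platelet markers (-0.31 and -0.36). With the 7S share as a covariate the mean difference became 0.43 ± 0.30 (SE) for histones, 0.02 ± 0.12 for ribosomal proteins, -0.06 ± 0.16 for MHC class II genes and -0.16 ± 0.24 for plasma cell markers. It became -0.41 ± 0.27 for cytotoxic lymphocyte markers and -0.10 ± 0.10 for nuclear oxidative phosphorylation genes. For the rest it was 0.59 ± 0.26 for classical monocyte markers, -0.26 ± 0.22 for platelet markers, -0.28 ± 0.31 for erythroid markers and -0.39 ± 0.21 for cell cycle genes.

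**Figure D2:**
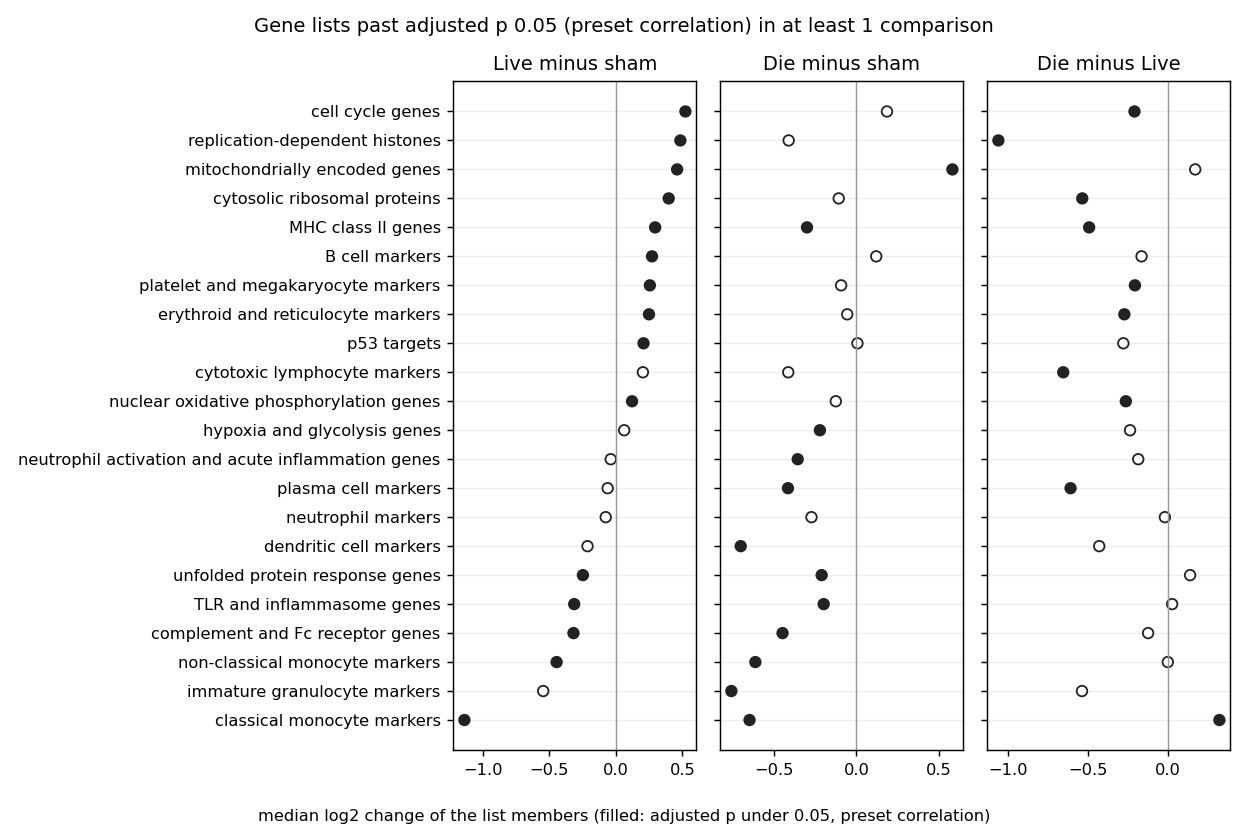
Median log2 change of each list's members for 3 comparisons, filled where the list passed with the preset correlation. Classical monocyte markers had medians of -1.14 in Live and -0.65 in Die animals against sham, and 0.32 for Die against Live.

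**Figure D3:**
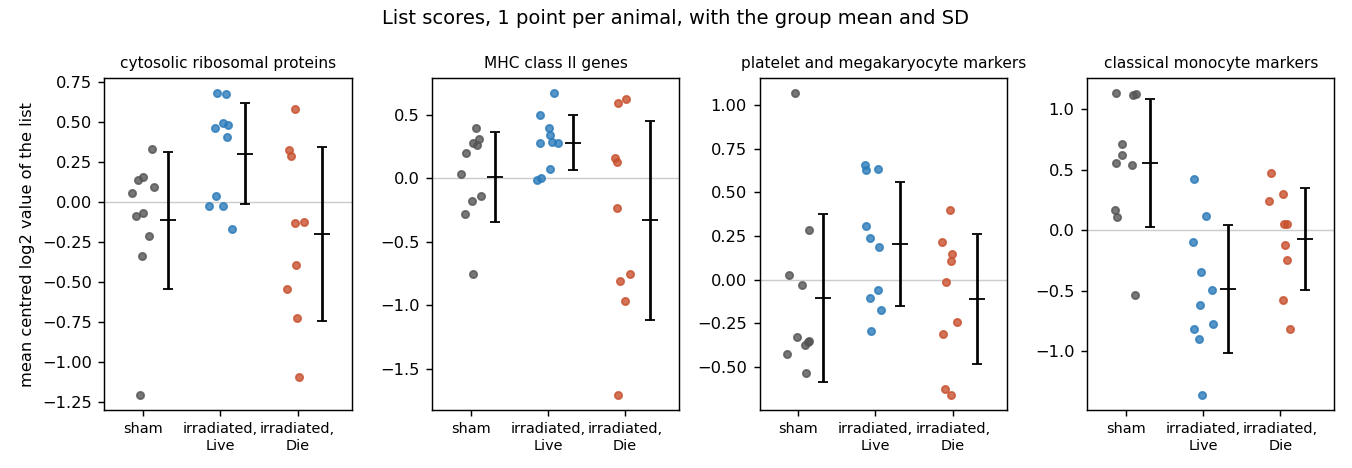
Mean centred log2 value of 4 lists in each animal by group, with the group mean and SD. The classical monocyte score was 0.55 ± 0.53 in sham, -0.49 ± 0.53 in Live and -0.07 ± 0.42 in Die animals.

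Several of these lists moved with the 7S RNA share, which was 13.3 percentage points lower in Die than in Live animals (exact permutation test, p = 0.0126, adjusted p = 0.0758 over 6 measures). The ribosomal protein score followed the log2 of that share over 29 libraries with Pearson's r = 0.886 and Spearman's coefficient = 0.802, both with a permutation p of 1e-05, the smallest that 100000 permutations can give (adjusted p = 3.33e-05 over 10 relations). Without the libraries farthest from the median, sham replicate 1 and Die replicate 14, r was 0.790, and within groups it was 0.913 in sham, 0.741 in Live and 0.874 in Die animals. The relation also held for histones (r = 0.906, Spearman's coefficient = 0.816, both with permutation p = 1e-05, adjusted p = 3.33e-05, r = 0.848 without those libraries), with r = 0.961 in sham, 0.899 in Live and 0.862 in Die animals. For MHC class II genes r was 0.846 and Spearman's coefficient 0.725 (both with permutation p = 1e-05, adjusted p = 3.33e-05, r = 0.778 without those libraries), but within Live animals r was 0.000682, against 0.874 in sham and 0.931 in Die animals. Plasma cell markers had r = 0.727 and Spearman's coefficient = 0.591 (permutation p = 0.00012 and p = 0.00092, r = 0.674 without those libraries), with r = 0.554 in sham, 0.298 in Live and 0.814 in Die animals. Cytotoxic lymphocyte markers had r = 0.633 and Spearman's coefficient = 0.583 (permutation p = 0.00048 and p = 0.00109, r = 0.704 without those libraries), with 0.237, 0.406 and 0.668 in the same order. Nuclear oxidative phosphorylation genes had r = 0.576 and Spearman's coefficient = 0.469 (permutation p = 0.00106 and p = 0.0105, r = 0.433 without those libraries), with 0.402, 0.0836 and 0.668 in that order. For classical monocyte markers r was -5.71e-05 and Spearman's coefficient -0.193 (permutation p = 1.0 and p = 0.313), but within groups r was 0.671 in sham, -0.201 in Live and 0.144 in Die animals. For platelet markers the coefficients were 0.233 and 0.251 (p = 0.223 and p = 0.190), with r of 0.159, 0.495 and -0.189 within groups. For erythroid markers they were 0.0268 and 0.0276 (p = 0.891 and p = 0.887), with 0.0421, 0.269 and -0.282 within groups. For cell cycle genes they were 0.291 and 0.377 (p = 0.125 and p = 0.0448, the latter with an adjusted p of 0.0640), with -0.0295, 0.648 and -0.0764 within groups.

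**Figure D4:**
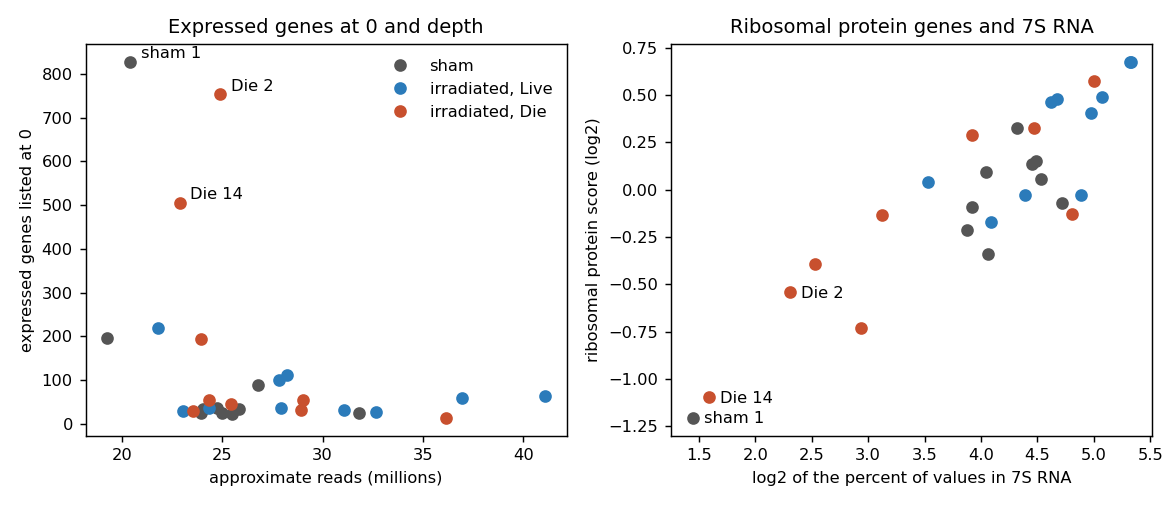
Left, number of expressed genes listed at 0 against approximate reads (M); right, ribosomal protein score against the log2 of the percent of values in 7S RNA, 1 point per library. Sham 1, Die 2 and Die 14 had 828, 754 and 506 expressed genes at 0, and the score followed the 7S share with r = 0.886.

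Of 24310 genes tested with limma for Die against Live, 0 passed, and 2514 had an unadjusted p under 0.05. The count was 1 without Die replicate 4.

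The classifier fixed in advance did not separate Die from Live animals beyond permuted outcomes. With 20 genes chosen inside each fold, 3 of 9 Die and 7 of 10 Live animals were assigned correctly, a balanced accuracy of 51.7% (permutation p = 0.455), against a median of 47.2% with permuted outcomes. With 5 genes it was 73.3% (permutation p = 0.218), with 50 genes 51.7% (permutation p = 0.485) and with 200 genes 62.8% (permutation p = 0.208). Without the 3 libraries with many genes at 0 it was 49.3% (permutation p = 0.376).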

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

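Tests chosen only after the result was seen were those on the 3 libraries with many genes at 0, the comparison of monocyte with lymphocyte scores, the comparison of depth and the counts over other divisions of the samples, and the 7S covariate itself was added after the library measures were seen.

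The first pattern is the fall of classical monocyte markers in irradiated animals, by a median of 0.85 on the log2 scale. Without the 3 libraries with many genes at 0 the median was -0.99, and with the 7S RNA share as a covariate it was -0.89, which argues against either as the whole cause. A lower share of all white cell RNA would lower lymphocyte markers alike, but the monocyte score minus the mean of the B and T cell scores was lower by 0.95 in irradiated animals (difference -0.95, permutation test, p = 0.00032). A candidate explanation that stays open is biological, a response to irradiation by day 120, which may be fewer monocytes in blood or lower expression of these genes per cell. These alternatives were not tested, as no cell counts were used here. The library numbers run through all sham animals first and then all irradiated animals. If handling followed these numbers, its effect cannot be told apart from that of irradiation.

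The second pattern is the lower ribosomal protein score in Die than in Live animals, with a mean difference of -0.50 ± 0.20 (SE). The score was -0.12 ± 0.43 (SD) in sham, 0.30 ± 0.31 (SD) in Live and -0.20 ± 0.54 (SD) in Die animals. Live was thus the group farther from sham, and Die minus sham was -0.09 (exact permutation test, p = 0.697). With the 7S RNA share as a covariate the difference between Die and Live was 0.02 ± 0.12 (SE), with a slope of 0.41 ± 0.05 (SE) per log2 of the share. A difference in library composition may therefore account for it. Without the 3 libraries the mean difference was -0.33 (exact permutation test, p = 0.0977), and whether those libraries carry it cannot be told apart, as the value lies between those that the 2 predictions named. These 3 libraries also had the lowest 7S shares, at most 4.97% against at least 5.78% elsewhere, so the 2 explanations overlap. What sets the 7S share is open, and a link of that share with outcome is among the open explanations, since the share was 13.3 percentage points lower in Die than in Live animals.

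The third pattern is the 3 libraries in which many expressed genes were at 0. Low sequencing depth alone is argued against by the trend of such genes with reads over the other 26 libraries, whose 95% prediction limits were 320, 229 and 262 genes against 828, 754 and 506 in sham replicate 1, Die replicate 2 and Die replicate 14. The smallest ratio to the limit was 1.93. The trend itself was weak (r = -0.316 between the log2 values). The 3 libraries were picked for their genes at 0 and left out of the fit, so lying above the limits follows in part from that choice. The test of the trend replaced a count of libraries with fewer reads than any of the 3, which found 1, with 19.3 M reads and 195 such genes. Fewer reads than in Die replicate 2 were found in 10 others, with 24 to 220 such genes, but in only 2 others than in Die replicate 14 and 1 than in sham replicate 1, so the limits are least sure for these. A low number of distinct molecules could give zeros at random among genes of like abundance. Sham replicate 1 and Die replicate 2 shared 266 genes at 0 against 175 expected within abundance bins, a ratio of 1.52, and the ratios of Die replicate 14 with these were 1.86 and 1.65. The ratio set for the test lies between the bounds set beforehand, so this explanation cannot be told apart from a shared loss of particular genes. Actb was 236018 to 321200 in the 3 libraries and 72661 to 175347 elsewhere, and no biological explanation was tested.

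Other divisions of the samples into groups of the same sizes, 100 with the real one included, were fitted in the same way. For irradiated against sham 1 division gave as many genes, the real one with 4 (highest other 2), which argues against chance for that count. As many lists came from 4 divisions (real 14, highest other 16), so chance is unlikely for the lists but cannot be excluded. For Live against sham 1 division gave as many genes (real 10, highest other 7), which argues against chance for that count. As many lists came from 2 divisions (real 15, highest other 16), so chance is again unlikely for the lists but cannot be excluded. For Die against sham 9 gave as many lists (real 12, highest other 18) and for Die against Live 26 (real 10, highest other 17), so chance cannot be excluded for these. For genes all 100 divisions gave as many in both (real 0, highest other 0 and 391), which tests nothing, as any division reaches a count of 0. The division with 391 genes points to a structure of the samples, which was not examined. Random divisions gave a median of 6 lists with the preset correlation in each comparison, so several lists pass that test by chance alone in these libraries.

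A sample was far from the others of its group, by the gap to its nearest neighbour over the whole range of the group, in 31 of 258 tests. Chance does so in about 1 in 20 groups, or 12.9 of 258, and 20 of the 31 fell in the 3 libraries above. Sham replicate 1 was lowest for apoptosis genes (0.85), histones (0.76), Cd3e (0.70), dendritic cell markers (0.69), Cd79a (0.68), hypoxia genes (0.66), non-classical monocyte markers (0.61), type I interferon genes (0.58), ribosomal proteins (0.56), 7S share (0.51) and inflammatory cytokines (0.48). It was highest for expressed genes at 0 (0.79), Mysm1 (0.48) and Ubxn4 (0.48). Die replicate 2 was lowest for cytotoxic lymphocyte markers (0.59), unfolded protein response genes (0.58), T cell markers (0.57) and basophil markers (0.54) and highest for Slc25a40 (0.51), and Die replicate 14 was lowest for non-classical monocyte markers (0.73). Sham replicate 10 was highest for cell cycle genes (0.51), Elf2 (0.50) and platelet markers (0.49). Live replicate 5 was highest for expressed genes at 0 (0.56) and lowest for histones (0.49) and neutrophil markers (0.47). Live replicate 7 was lowest for regulatory T cell markers (0.56), Live replicate 18 highest for heme enzymes (0.51), Die replicate 4 highest for Dyrk4 (1.0) and cell cycle genes (0.62), and Die replicate 16 highest for reads (0.54). For Dyrk4 the other Die animals were tied, so the ratio could only be 1.0.

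For 10 lists the test of the difference between Die and Live animals passed with the preset correlation, but for 0 with an estimated correlation and for 0 with animals as the unit. The median differences were 0.32 for classical monocyte markers, -0.21 for platelet markers, -0.21 for cell cycle genes, -0.26 for nuclear oxidative phosphorylation genes, -0.27 for erythroid markers and -0.49 for MHC class II genes. They were -0.54 for ribosomal proteins, -0.61 for plasma cell markers, -0.65 for cytotoxic lymphocyte markers and -1.06 for histones.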

How the results depend on the processing

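Tests chosen after the data were seen were the removal of the 3 libraries with many genes at 0, a minimum mean of 50, a pseudocount of 10, the 7S share as a covariate and the permutation of animals. In the order irradiated, Live and Die against sham, the counts of genes were 4, 10 and 0 as reported. They were 481, 716 and 8 with array weights, 28, 39 and 8 with composition covariates, 1, 3 and 1 with the number of reads as a covariate, and 358, 620 and 2 with array weights without the 3 libraries. For irradiated and Live against sham they were 62 and 115 without the 3 libraries, 10 and 40 with a minimum mean of 50, where 11519 genes were tested, 40 and 73 with the 7S share, 1 and 4 at an adjusted p under 0.01, and 0 and 0 with the replicate number as a block. The block fit held only animals whose number occurs in both groups, so it also had fewer libraries. Animals of 1 number showed no likeness, with correlations from -0.0801 to 0.00966 over 10 pairs. With 1 library left out the counts ranged from 1 to 66, from 5 to 50 and from 0 to 20, and from 0 to 1 for Die against Live. Without the 3 libraries, with array weights and with the 7S share, the 4 and 10 genes called in the first 2 comparisons were all called again. Beyond the stricter threshold, the cause was not tested. Lists past the threshold numbered 14, 15, 12 and 10 with the preset correlation over the 4 comparisons, 3, 1, 0 and 0 with an estimated one, and 1, 1, 0 and 0 with animals as the unit. For Die against sham they were 6 at an adjusted p under 0.01, 7 with a minimum mean of 50, and between 7 and 17 with 1 library left out. List medians reversed for Live against sham in B cell markers (-0.056), MHC class II genes (-0.147) and histones (-0.108) with composition covariates, in histones with reads as a covariate (-0.113) and with the 7S share (-0.171), and for Die against Live in histones with the 7S share (0.353). The correlation of changes, 0.359, became -0.103 and 0.0376 with sham animals divided. Of values for named genes under all alternatives, 3143 kept direction and side of the threshold. In 57 a gene not called as reported changed direction, 78 came to pass and 93 no longer passed. For lists 6997 kept their side of the threshold, where lists that did not pass may have changed direction. Another 4 changed direction and came to pass, 188 came to pass in the same direction, 211 no longer passed, and 6 reversed as named above. Alternatives named before the data were examined but not run were the DESeq2 Wald test and DESeq2 size factors, which need counts, also for lists. Surrogate variables, likewise named beforehand, were not run either. The fit to only the groups compared has no meaning for irradiated against sham, and a replicate block has none for Die against Live, which share no numbers. What depth limits was not tested, as read counts were not recovered, and 17811 symbols were at 0 in every library.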

Other observations

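Tests chosen only after the result was seen were those with the 7S RNA share as a covariate, and the single genes were picked after their values were seen.

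Between the irradiated groups, cell type lists moved in different ways when the 7S RNA share was taken into account. The mean difference of classical monocyte markers, Die minus Live, was 0.42 ± 0.23 (SE) before and 0.59 ± 0.26 (SE) with the share as a covariate, and 7 of 9 Die animals lay above the Live median. Platelet and megakaryocyte markers were at -0.31 ± 0.19 (SE) before and -0.26 ± 0.22 (SE) after, and cell cycle genes at -0.44 ± 0.18 (SE) before and -0.39 ± 0.21 (SE) after. In both lists Live was the group with higher scores, and Die animals lay near sham. Platelet scores were -0.10 in sham, 0.20 in Live and -0.11 in Die animals, and cell cycle scores were -0.19, 0.31 and -0.13 in that order. MHC class II genes were at -0.61 ± 0.23 (SE) before and -0.06 ± 0.16 (SE) after, cytotoxic lymphocyte markers at -0.81 ± 0.26 (SE) before and -0.41 ± 0.27 (SE) after, and plasma cell markers at -0.70 ± 0.27 (SE) before and -0.16 ± 0.24 (SE) after.

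Other lists hold single genes that passed when adjusted over the list alone and not over all genes. Cd34, a surface protein of stem and progenitor cells, had a log2 change of 1.75 ± 0.55 (SE, adjusted p = 0.0319 over the list alone, 0.356 over all genes) in irradiated animals. Apaf1, a core protein of the apoptosome, was at -0.62 ± 0.15 (SE, adjusted p = 0.00364 over the list alone, 0.160 over all genes). Between Die and Live animals, Atr, a kinase of the DNA damage response, was at 0.76 ± 0.20 (SE, adjusted p = 0.0137 over the list alone, 0.348 over all genes). Gpx4, which reduces lipid peroxides, was at -0.96 ± 0.25 (SE, adjusted p = 0.00949 over the list alone, 0.348 over all genes), and Fcer1a, a receptor subunit for IgE on basophils and mast cells, at -3.27 ± 0.92 (SE, adjusted p = 0.0118 over the list alone, 0.348 over all genes).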
